A study of Homo sapiens with 8 samples.

How the data were processed

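RNA sequencing of K562 cells with an inducible SF3B1 transgene gave 8 libraries, which the labels place in 4 groups (K700E_induced, K700E_uninduced, WT_induced and WT_uninduced) with replicates 1 and 2 each. Cells grew in medium with 10% serum, per the labels' protocols, and doxycycline was given at 1 ug/ml for 48 h. Ribosomal RNA was depleted by an RNase H method before library preparation, per the labels' protocols. Nothing says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

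The deposited values are FPKM per transcript, made by the authors with CASAVA, TopHat and Cufflinks on hg19, per the submitters' processing notes; their versions and settings are not given in the sources used here. Each library has its own list of transcripts, with 43497 reference transcripts in each and between 24926 and 45570 transcripts assembled in that library. Most assembled transcripts were unspliced and about 200 nt long (median 202 to 211 nt). Cufflinks divides reads among overlapping transcripts by estimation, so a transcript can be listed at 0 in one library and take the whole gene in another. Read counts are not used here, and depth is known only through the coverage per FPKM in the same lists, between 3.30 and 4.79.

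A gene's value was the sum of FPKM over its reference transcripts on the primary chromosomes and over the assembled spliced transcripts assigned to it. An assembled spliced transcript of 300 nt or more went to the gene sharing more of its introns than any other gene. Ties were left out. Unspliced assembled transcripts of 300 nt or more were joined to a single-exon reference transcript on the same strand where each covered 90% of the other. Of 40801 accessions, 33391 were named by the files and 7087 by a table of current gene names, and 228 of the 323 others by shared introns; 9 were renamed because their current gene lies on another chromosome. This gave 23502 genes. Coordinates are those of the files, on hg19.

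Libraries were scaled by median-ratio factors from 7574 genes at 1 FPKM or more in all libraries, with factors between 0.99 and 1.04. The 11349 genes with a mean scaled FPKM of 1 or more were tested as log2(FPKM + 0.5) with limma 3.58.1 (trend, group means, all 8 libraries) in R 4.3.3, in 5 comparisons, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. Fold changes are on this scale and understate the change of low genes. No fold is given against a group listed at 0. Transcript shares were tested as log2 ratios of a transcript to the rest of its gene, for transcripts with a mean share of 5% to 95%, matched between libraries by their introns. Tandem acceptors were tested as log2 ratios of FPKM on the upstream and the downstream site, and their share per library by an exact permutation test of the K700E_induced libraries against the other 6. Fixed gene lists, 27 in number, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives; 25 had 3 or more measured members, the lymphoid markers had 2 and the mitochondrially encoded mRNAs had 0. Tables were built with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

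Genes were named by a rule set before the data were examined. It took SF3B1 first, then per comparison up to 8 genes with the highest and 8 with the lowest fold change among those past the threshold, with a transcript of 300 nt or more and no overlap between the groups. Up to 3 members of each list past the threshold followed. TAL1, GATA1, KLF1, ALAS2, MAP3K7, SLC25A37, HBG1, HBZ, HBE1 and AHSP were always named, as were the transcripts of TAL1, MAP3K7 and BRD9 and the 8 tandem pairs with the smallest p in each of 2 comparisons. Some items this rule names are not reported here. Because so few genes passed, the 6 genes with the smallest p per comparison among those above 0 in all libraries, with a mean of 20 FPKM and 300 nt or more, were added after the values were seen.

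The fits were tested on simulated data with the means of these libraries and limma's moderated spread, drawn as independent normal noise. That spread is already drawn toward the spread of other features, so it varies less between features than the spread observed. The draws held no zeros, no all-or-none assignments and no correlation between genes, unlike what the real data can hold. The shares called may therefore not hold for these libraries, and the list result does not cover correlated members. For K700E induction over 11349 genes, 82% of genes moved by 6 log2 units were called, 50% of those moved by 4 and 4% of those moved by 2, and 6 of 11149 unmoved genes. Over 24462 transcripts, 90.9% of those moved by 16 log2 units were called, 13.4% of those moved by 8 and 0% of those moved by 4, and 8 of 24262 unmoved transcripts, with 1 call in the unmoved WT induction. Over 491 tandem pairs the shares were 100%, 53.8% and 7.14% for the same sizes, and 0 of 451 unmoved pairs were called. A heme synthesis list moved by 1 log2 unit was called in 20 of 20 draws, and 2 of 460 tests of unmoved lists were called.

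Other settings tried were pseudocounts of 0.1 and 1, no filter and a filter at 5 FPKM, no scaling and upper-quartile scaling, a block on the replicate number, fits of the compared groups alone, genes of 300 nt or more, no trend, acceptors up to 50 nt apart and leaving out each library in turn. Genes above 0 in all libraries, reference transcripts alone, a block on line and replicate number together, the mean upstream share and the counts of assembled acceptors were added after the data were seen.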

Results

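RNA sequencing of K562 cells, a human erythroleukaemia line with early erythroid features, gave 8 libraries in 4 groups of 2. The cells carried a doxycycline-inducible transgene for SF3B1, a component of the U2 small nuclear ribonucleoprotein that recognises the branch point, either in its wild-type form (WT) or with the K700E substitution found recurrently in myelodysplastic syndromes. Each line was left uninduced or was induced with 1 ug/ml doxycycline for 48 h, and the stated aim was to follow changes in gene expression and splicing. The libraries were made from total RNA after depletion of ribosomal RNA. Read totals are not used here, but the deposited transcript models give coverage per unit of FPKM, which ranged from 3.30 in WT_induced replicate 2 to 4.79 in WT_induced replicate 1. For long reference transcripts between 10 and 100 FPKM the typical half-width of the deposited interval was 6.16% to 6.94% of the value. This is an error of estimation within a library only, and short and assembled transcripts were left out of it. Across the 8764 genes above 0 in all libraries, those of the same group correlated at a mean r of 0.842 and libraries of different groups at 0.839, so libraries of a group were hardly more alike than others. Of 11349 genes tested, 2585 were listed at 0 in at least 1 library.

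SF3B1 itself, at 198256698 to 198299771 on chromosome 2 of hg19, had similar total levels in all groups. Its FPKM was 34.3 ± 7.45 (SD, n = 2) in K700E_induced, 32.5 ± 2.98 (SD, n = 2) in K700E_uninduced, 32.0 ± 6.57 (SD, n = 2) in WT_induced and 34.7 ± 4.23 (SD, n = 2) in WT_uninduced. The log2 fold change on induction was 0.06 (SE 0.37) in the K700E line and -0.13 (SE 0.37) in the WT line, and limma gave an adjusted p of 1 for both. The difference between K700E_induced and WT_induced was 0.09 (SE 0.37), that between the uninduced lines was -0.10 (SE 0.37), and the interaction was 0.19 (SE 0.52). Each of these 5 values took the opposite sign when some single library was left out. Transgene and endogenous reads are summed in these values, as far as the transgene carries the reference sequence, and the values do not separate the K700E allele. They show no detectable rise of SF3B1 with doxycycline in either line, so induction of the transgene was not checked here, and "induced" names the treatment given in the labels.

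**Figure D1:**
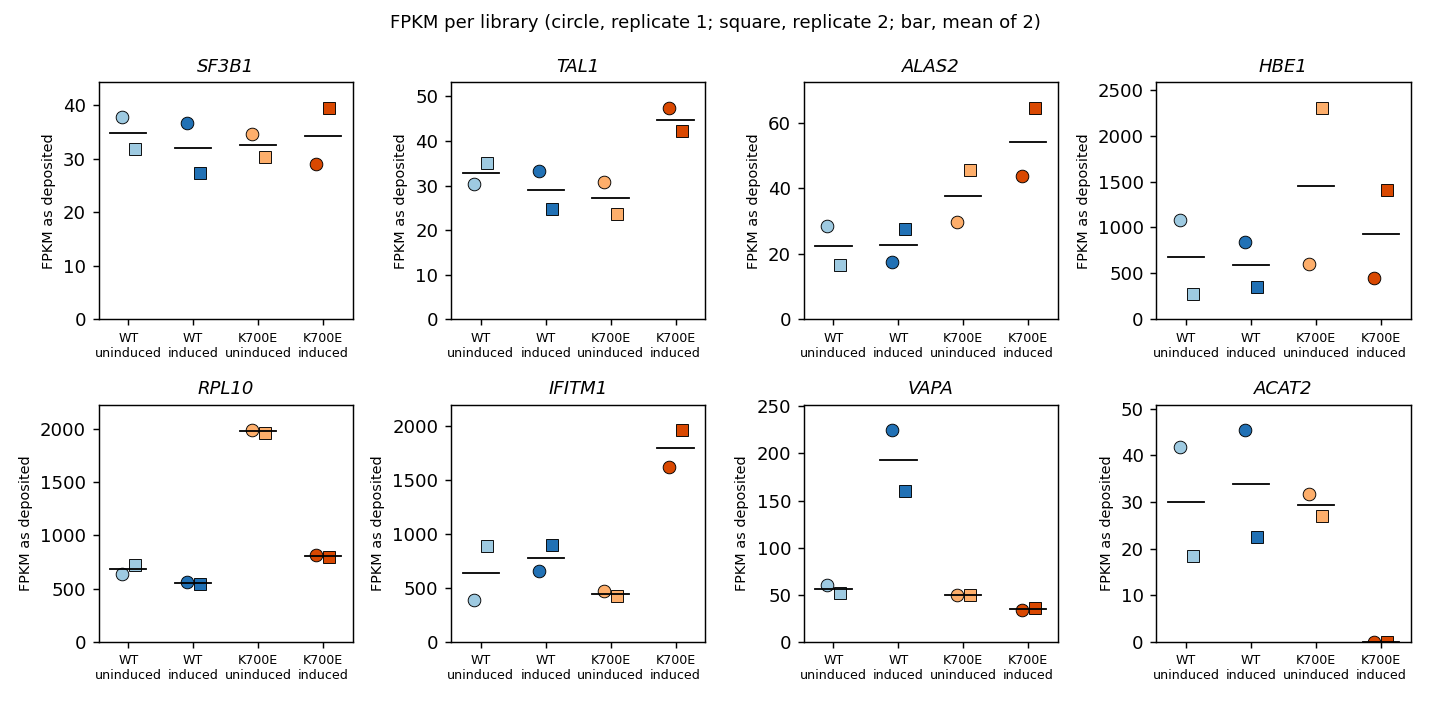
FPKM as deposited (linear axis) of 8 genes in each library, by group; circles are replicate 1, squares replicate 2 and bars the mean of 2. SF3B1 lies between 27.3 and 39.5 in all 8 libraries, HBE1 ranges from 279 to 2303 with wide gaps within each group, and ACAT2 is listed at 0 in both K700E_induced libraries.

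On induction of the K700E transgene no erythroid gene passed the test. TAL1, a transcription factor of the erythroid programme, was at 44.8 ± 3.77 FPKM (SD, n = 2) after induction and 27.2 ± 5.07 before, a log2 fold change of 0.72 (SE 0.36). The 2 induced libraries lay above the 2 uninduced ones, yet limma's adjusted p was 1. GATA1 (0.22, SE 0.25), KLF1 (0.09, SE 0.58) and ALAS2, the erythroid enzyme that starts heme synthesis (0.53, SE 0.47), also had an adjusted p of 1. The same held for the globin genes HBG1 (-0.39, SE 0.42), HBZ (-0.05, SE 0.58) and HBE1 (-0.55, SE 0.89). The kinase gene MAP3K7 had a log2 fold change of -0.26 (SE 0.63) and the mitochondrial iron importer gene SLC25A37 one of -0.04 (SE 0.41), again with adjusted p of 1. With reference transcripts alone SLC25A37 was at 4.58, MAP3K7 at -1.85, TAL1 at 0.41, KLF1 at 0.42, ALAS2 at 0.33 and GATA1 at -0.011. That setting drops assembled transcripts, which held all of TAL1 in some libraries. Its values can therefore reflect how reads were assigned rather than a change in level. AHSP, the alpha globin chaperone gene, was listed at 0 in 7 libraries and at 6.69 FPKM in K700E_induced replicate 2.

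Only 1 gene passed the threshold in this comparison, the microRNA precursor MIR4461, with a limma adjusted p of 8.05e-06. It was listed at 62742 and 66035 FPKM in the K700E_induced libraries and at 0 in the other 6. Its model spans 74 nt, so it fell outside the naming rule and was chosen after its values were seen. At an unadjusted p under 0.05 there were 533 genes, where chance alone gives 567. Among genes above 0 in all libraries, 6 were chosen after their values were seen to show the sizes involved. RPL10, a ribosomal protein gene, was at 806 ± 11.9 FPKM (SD, n = 2) after induction and 1975 ± 17.5 before, a log2 fold change of -1.29 (limma adjusted p 0.75). IFITM1, an interferon-inducible membrane protein gene, was at 1790 ± 238 (SD, n = 2) against 445 ± 35.2, a log2 fold change of 2.01 (adjusted p 0.899). The cyclin-dependent kinase subunit gene CKS2 (2.25) and LSM14B (2.21) were higher, and PPP2R5A, a phosphatase regulatory subunit gene (-2.01), and TIMP1, a metalloproteinase inhibitor gene (-1.13), were lower, with adjusted p from 0.899 to 0.98. With reference transcripts alone RPL10 took the opposite sign (1.22) and so did LSM14B (-0.67).

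By gene list, none of 25 lists passed camera's adjusted threshold on K700E induction, and 4 had an unadjusted p under 0.05; with an estimated correlation and by fry, 0 lists passed and 0 had an unadjusted p under 0.05. Of 27 replication-dependent histone genes measured, 20 had a positive and 7 a negative log2 fold change, with a median of 0.40 (camera adjusted p 0.109). For all 4 lists the adjusted p was 0.918 with an estimated correlation. Of 25 genes for iron and iron-sulfur metabolism, 16 lay below 0, with a median of -0.25 (camera adjusted p 0.21). All 5 myeloid markers measured lay below 0, with a median of -1.30 (camera adjusted p 0.109); CD68 was at 3.26 and 5.73 FPKM in the K700E_induced libraries and at 27.1 and 15.9 in the K700E_uninduced ones. All 7 stromal and epithelial markers lay below 0 as well (median -0.77, camera adjusted p 0.109), among them the keratin gene KRT8, at 319 and 305 FPKM after induction and 629 and 539 before. CD68 and KRT8 were chosen after their values were seen. No member of these 4 lists passed over all genes, and adjusted over the list alone 1 myeloid marker was lower. Of 30 measured genes known to be misspliced in SF3B1 mutants, 17 lay above and 13 below 0 (camera adjusted p 0.881), and of 21 genes for U2 components and branch point recognition, 9 lay above and 12 below 0 (camera adjusted p 0.881).

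Induction of the wild-type transgene likewise brought no erythroid gene past the threshold. TAL1 was at 29.1 ± 6.06 FPKM (SD, n = 2) in WT_induced and 32.7 ± 3.22 in WT_uninduced. SLC25A37 was at 55.4 ± 7.41 FPKM (SD, n = 2) after induction and 183 ± 27.1 before, a log2 fold change of -1.72 (SE 0.41; limma adjusted p 0.996), which became positive (2.90) with reference transcripts alone. The one gene past the threshold was VTRNA1-3, a vault RNA of 88 nt, with a limma adjusted p of 0.00275. It was listed at 567932 and 32104 FPKM in the WT_induced libraries and at 0 in the other 6, and was named after its values were seen. Its call was lost when any library outside WT_induced was left out. Keeping the call without either WT_induced library shows little. No group then had any spread for this gene, so its p rested on the spread of other genes. With the compared groups alone the adjusted p was 0.0536. There were 489 genes at an unadjusted p under 0.05. Among genes above 0 in all libraries, again chosen after their values were seen, VAPA, a membrane contact protein of the endoplasmic reticulum, was at 193 ± 45.3 FPKM (SD, n = 2) against 56.1 ± 5.96, a log2 fold change of 1.75 (adjusted p 0.683), which turned to -0.67 with reference transcripts alone. MPST, a sulfurtransferase gene, had a log2 fold change of 2.07 (adjusted p 0.735). THOC1, a component of the mRNA export complex THO (-2.19), GABRE (-2.21) and RPL36AL (-1.50) were lower, each with an adjusted p of 0.996. No gene list passed camera's threshold, none had an unadjusted p under 0.05, and the smallest adjusted p was 0.827.

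Between the induced lines, 3 genes passed the threshold in K700E_induced against WT_induced. MIR4461 was higher (limma adjusted p 8.05e-06) and VTRNA1-3 lower (adjusted p 0.00137, but 0.0588 without K700E_induced replicate 1). ACAT2, which encodes a cytosolic thiolase of sterol synthesis and lies at 160182989 to 160200087 on chromosome 6, was listed at 0 in both K700E_induced libraries. It was at 45.4 and 22.5 FPKM in WT_induced, 31.6 and 27.0 in K700E_uninduced and 41.7 and 18.4 in WT_uninduced (limma adjusted p 0.041). The ACAT2 call was lost whichever library was left out, with adjusted p from 0.0894 to 0.409, and under 8 other settings. Its end overlaps that of TCP1, on the opposite strand, where reads can be divided wrongly. There were 596 genes at an unadjusted p under 0.05.

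Genes above 0 in all libraries and chosen after their values were seen did not pass in that comparison. VAPA was at 34.8 ± 1.28 FPKM (SD, n = 2) in K700E_induced and 193 ± 45.3 in WT_induced, a log2 fold change of -2.44 (limma adjusted p 0.12). The mitochondrial enzyme gene ACSM3 had a log2 fold change of -2.01 (adjusted p 0.263) and the cobalamin enzyme gene MMAB one of 4.46 (adjusted p 0.272). PGGHG (2.35), the lysosomal gene CLN3 (-3.17) and LOC728323 (3.30) had adjusted p from 0.36 to 0.369. The VAPA value was -0.0075 with reference transcripts alone, that of LOC728323 turned to -1.68, and MMAB was at 0.78, PGGHG at 0.20 and CLN3 at -1.41. By gene list, 7 of 25 had an unadjusted p under 0.05 and none passed camera's adjusted threshold, the smallest adjusted p being 0.0851. All 8 globin genes measured lay above 0 (median 0.56), as did 13 of 18 heme synthesis genes (median 0.55), 16 of 20 cholesterol synthesis genes (median 0.36) and 22 of 25 genes of the integrated stress response (median 0.34), each with an adjusted p of 0.0851. Before induction 7 of the 8 globin genes already lay above 0 (median 0.46, camera adjusted p 0.826), and their interaction had a median of 0.05 (camera adjusted p 0.765). The direction of some globin genes turned with the replicate: HBE1 was at 453 FPKM in K700E_induced against 840 in WT_induced in replicate 1, and at 1412 against 351 in replicate 2. That of HBG1 did not turn, at 1765 against 1135 FPKM in replicate 1 and 2586 against 1933 in replicate 2. Of the other lists, 12 heme synthesis genes, 14 cholesterol synthesis genes and 17 genes of the integrated stress response lay above 0 before induction as well, and their interactions had camera adjusted p of 0.408, 0.915 and 0.49. Of 5 myeloid markers 4 lay below 0 (median -0.48, adjusted p 0.0851), of 47 nuclear genes of the respiratory chain 29 lay above 0 (median 0.11, adjusted p 0.102) and of 25 genes for iron and iron-sulfur metabolism 19 lay below 0 (median -0.31, adjusted p 0.155). For these 7 lists the adjusted p was 0.679 with an estimated correlation, and by fry 0 lists passed. ALAS2 was at 54.2 ± 14.6 FPKM (SD, n = 2) in K700E_induced and 22.5 ± 6.94 in WT_induced (limma adjusted p 0.92). It was at 37.6 ± 11.3 FPKM in K700E_uninduced and 22.5 ± 8.31 in WT_uninduced, and its interaction was 0.52 (SE 0.66, limma adjusted p 0.999). The asparagine synthetase gene ASNS was at 278 and 214 FPKM in K700E_induced against 118 and 159 in WT_induced. ASNS was chosen after its values were seen. No member of these 7 lists passed over all genes, and adjusted over the list alone 2 myeloid markers were lower. HBA1 and HBA2, and HBG1 and HBG2, are near-identical copies whose reads may have been divided between them.

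Before induction, no gene differed between the lines by limma (K700E_uninduced against WT_uninduced), with 525 genes at an unadjusted p under 0.05. RPL10 was among the genes that shared the smallest adjusted p, 0.215. It was at 1975 ± 17.5 FPKM (SD, n = 2) in K700E_uninduced and 682 ± 61.3 in WT_uninduced, a log2 fold change of 1.53. Without a filter on low values RPL10 passed (limma adjusted p 0.0489), and with reference transcripts alone it turned to -0.97. MYLIP, a ubiquitin ligase gene (2.17), MPST (1.91), PSMG4 (2.22), ABCB8 (1.89) and RGS14 (-2.29) had adjusted p from 0.687 to 0.95; like RPL10 they were chosen after their values were seen. With reference transcripts alone ABCB8 turned to -1.20, RGS14 was at -0.14 and MYLIP at 0.60. No gene list passed camera's threshold, and 1 had an unadjusted p under 0.05, the stromal and epithelial markers, of which 5 of 7 lay above 0 (adjusted p 0.75, or 0.982 with an estimated correlation; adjusted over the list alone, 2 members were higher).

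The interaction asked whether induction acted differently in the K700E and WT lines, and 2 genes passed it. These were MIR4461 (limma adjusted p 0.000128) and VTRNA1-3 (adjusted p 0.02), both listed at 0 in 6 libraries. The first was lost without K700E_induced replicate 1 (adjusted p 0.0887) and the second when any single library outside WT_induced was left out (0.137 to 0.224). There were 482 genes at an unadjusted p under 0.05. The genes above 0 in all libraries that were chosen after their values were seen did not pass. VAPA (-2.26, adjusted p 0.831) and MPST (-2.70, adjusted p 0.882) were lower after K700E induction and higher after WT induction. LSM7, a component of the Sm-like complex (1.71), CKS2 (3.31) and the histone gene HIST1H4C (1.35) went the other way, and ELP2 had a value of -3.95, each with an adjusted p of 0.999. With reference transcripts alone the VAPA interaction was 0.16, so its opposite directions were lost, and that of ELP2 was -1.0. No gene list had an unadjusted p under 0.05 by camera (smallest adjusted p 0.408). Across the 11349 genes the log2 fold changes of the 2 inductions correlated at a Pearson r of 0.01 and a Spearman rho of 0.02. Genes are not independent replicates, so no p is given; no gene was called in both inductions.

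For splicing, 24462 transcripts of 7601 genes were compared by their share of the gene, and limma called none in any of the 5 comparisons. At an unadjusted p under 0.05 there were 910 on K700E induction, 968 on WT induction, 987 between the induced lines, 932 between the uninduced lines and 911 in the interaction. MAP3K7 showed an assembled form with 14 introns, from 91223292 to 91281603 on chromosome 6, which made up 60.3% and 79.8% of the gene in the K700E_induced libraries and 0% in the other 6. The adjusted p for its change on K700E induction was 0.901. In the K700E_induced libraries MAP3K7 had 14.7 and 6.66 FPKM on the reference acceptor at 91269934, and 0 on the acceptor 20 nt upstream of it. TAL1 was assigned wholly to an assembled transcript with 4 introns in K700E_induced, K700E_uninduced and WT_induced replicate 1, and wholly to the reference transcript NM_003189 in the other 5 libraries. In BRD9 no form was found in both K700E_induced libraries. Assignments of 0% or 100% were common, so the spread between replicates was wide.

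Tandem acceptors, where a donor joins 2 acceptors 10 to 30 nt apart, were the class in which SF3B1 hot-spot mutants are known to favour the upstream site. Of 491 such pairs, 1 passed on K700E induction, in YIPF2, a Golgi membrane protein gene on chromosome 19 (limma adjusted p 0.0185), and it also passed between the induced lines (adjusted p 0.019). From the donor at 11033947, on the minus strand, the acceptor at 11033868 took 100% in both K700E_induced libraries, at 52.0 and 57.8 FPKM, and 0% in the other 6, where the acceptor 17 nt downstream at 11033851 was used at 29.7 to 53.8 FPKM. The upstream acceptor is absent from the reference models. The interaction for YIPF2 did not pass (adjusted p 0.221), and the call on induction was lost when any single WT library or K700E_uninduced replicate 2 was left out (adjusted p 0.0506 to 0.071), and that between the induced lines when any single uninduced library was left out (0.0642 to 0.0858). Among 645 pairs of acceptors 31 to 100 nt apart, 1 pair passed on WT induction and 1 between the uninduced lines. PKMYT1 used its upstream acceptor at 19.4% and 31% in K700E_induced and 0% elsewhere (adjusted p 0.338 against WT_induced), and SHMT2 at 82.8% and 76.6% against 100% elsewhere (adjusted p 0.42). E2F3, ECI2, TMEM91 and MUC1 were among the other pairs with the smallest p in the interaction, at an adjusted p of 0.831. B4GALT3, TMEM91, NPTN, ATXN7L3 and BRE followed between the induced lines, with adjusted p from 0.659 to 0.794. Of 6 pairs in genes known to be misspliced in SF3B1 mutants, in PPP2R5A, SERBP1, DYNLL1, TMEM14C, MAP3K7 and ORAI2, none passed. Adjusted over these pairs alone, the p was 0.172 to 0.951 on K700E induction and 0.627 between the induced lines. The mean upstream share was higher in 5 of the 6 pairs and lower in 0 on K700E induction, and higher in 4 and lower in 0 on WT induction, in several pairs through 1 library. DYNLL1 used the upstream site at 27.2% and 19.1% in K700E_induced, 0% in both K700E_uninduced libraries, 0% and 43.8% in WT_induced and 24.4% and 16.6% in WT_uninduced. SERBP1 used it at 80.8% and 73.7% in K700E_induced, 67.7% and 17.8% in K700E_uninduced, 17.4% and 61.4% in WT_induced and 0% and 37.3% in WT_uninduced, so both K700E_induced libraries lay above the other 6. TMEM14C used it at 100% and 0% in K700E_induced, 74.0% and 0% in WT_induced and 0% in the 4 uninduced libraries. MAP3K7 used it at 92.8% in WT_induced replicate 1 and 0% in the other 7 libraries, and PPP2R5A at 76.1% in K700E_uninduced replicate 1 and 100% in the other 7. ORAI2 used it at 100% in K700E_induced replicate 2 and 0% in the 4 other libraries with a value.

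Over all pairs, the median upstream share was 0% in each of the 8 libraries, so this planned measure was saturated in the main setting (exact permutation p of 1 over 28 splits, two-sided). Under other settings with all libraries kept, its difference reached at most 13.2 points, and the smallest exact permutation p was 0.143. The mean share, computed after that was seen, was 40.2% and 40.1% in the K700E_induced libraries and 36.0% to 38.9% in the other 6. The difference was 2.61 percentage points (exact permutation p 0.0357, two-sided, the smallest the 28 splits allow), and it missed the threshold at p 0.0714 with pairs of 5 FPKM or more or with acceptors up to 50 nt apart. It also missed it without WT_uninduced replicate 1, K700E_uninduced replicate 2 or WT_induced replicate 2 (exact permutation p 0.0952 each). Means for acceptors 1 to 9 nt apart differed by 0.20 points (exact permutation p 0.893), those 31 to 100 nt apart by 0.71 (exact permutation p 0.786) and tandem donors by 0.07 (exact permutation p 0.964). Acceptors known only from the assembly and lying 10 to 30 nt upstream of a reference acceptor, also counted after the data were seen, numbered 24 and 28 in K700E_induced. They numbered 10 and 16 in K700E_uninduced, 19 and 14 in WT_induced and 14 and 12 in WT_uninduced. The exact permutation p was 0.0357, or 0.286 adjusted over the 8 kinds of site counted, where a single kind at the smallest p that 28 splits allow cannot pass. Pairs with such assembled acceptors, that of YIPF2 among them, also enter the mean upstream share. The count and the mean share are therefore not separate lines of evidence.

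**Figure D2:**
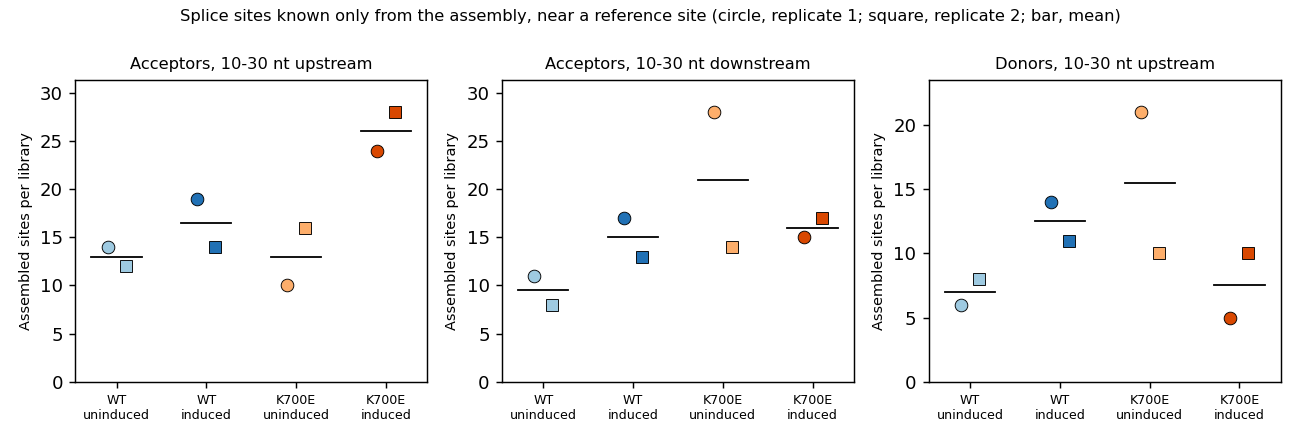
Number per library of splice sites known only from the assembly and lying 10 to 30 nt from a reference site, for upstream acceptors, downstream acceptors and upstream donors; circles are replicate 1, squares replicate 2 and bars the mean of 2. The K700E_induced libraries, with 24 and 28 upstream acceptors, lie above the other 6 (10 to 19), while they hold 15 and 17 downstream acceptors against 8 to 28, and 5 and 10 upstream donors against 6 to 21.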

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

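The test of transcript length was chosen only after the result was seen; the tests of gene overlap and of shared zeros were set before, but the margin by which the count of shared zeros had to miss its bound was set after.

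The interaction test called 2 genes, MIR4461 (limma adjusted p 0.000128) and VTRNA1-3 (adjusted p 0.0200). MIR4461 was listed above 0 in the K700E_induced libraries and VTRNA1-3 in the WT_induced libraries, and each was listed at 0 in the other 6. Groups listed at 0 in both libraries added no spread to the fit, so these p-values measure little of the variation between replicates. The call for MIR4461 was lost without K700E_induced replicate 1 (adjusted p 0.0887). The call for VTRNA1-3 was lost when any single library outside WT_induced was left out (adjusted p 0.137 to 0.224) and under 4 other settings (0.0544 to 0.113).

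All 3 genes called in any gene comparison, MIR4461, VTRNA1-3 and ACAT2, were listed at 0 in every library of at least 1 group. Very short transcripts are a candidate explanation for the first pair that stays open, since their length was known when it was tested: 2 of the 3 called genes were under 300 nt, against 79 of 11349 tested (Fisher's exact p 0.000143). Failed estimates at overlapping genes are a candidate explanation for ACAT2, which overlaps TCP1: among genes of 300 nt or more with a mean of 10 FPKM or more, 47.1% of the 329 listed at 0 somewhere overlapped another gene, against 26.5% of the 5810 above 0 throughout, an odds ratio of 2.48 (95% interval 1.97 to 3.12). A loss of expression in the induced K700E cells gained no evidence: 4 genes were at 0 in exactly both K700E_induced libraries, while the 24 pairs of libraries from different groups had a median of 4 and at most 11. The bound set beforehand against a loss was a count at or under that median, which was met, but not by more than its counting spread, so a loss stays open for ACAT2.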

How the results depend on the processing

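The mean upstream share, the counts of assembled acceptors, the restriction to genes above 0 in all libraries, reference transcripts alone and the block on line and number together were tests chosen after the data were seen. Counts of called genes were small and moved with the setting. Without a filter they were 28 on K700E induction, 13 on WT induction, 14 between the induced lines, 24 between the uninduced lines and 15 in the interaction. With genes of 300 nt or more, or genes above 0 in all libraries, they were 0 in all 5 comparisons. Both settings leave out the short RNAs by construction, and the second also ACAT2, which in the first was lost at the same fold (adjusted p 0.0959). Reference transcripts alone gave 2, 9, 5 and 4 calls in the first 4 comparisons. No trend gave 4 on WT induction, 7 between the induced and 6 between the uninduced lines, a pseudocount of 0.1 gave 2 on K700E induction, and the compared groups alone gave 0 on WT induction and 6 between the induced lines. Leaving out a library gave 1 to 7, 0 to 8, 3 to 11, 0 to 6 and 0 to 3 calls in the 5 comparisons, where the lone library of a group is assumed to vary like the others. The cause was not tested.

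SF3B1 ranged over leave-one-out fits from -0.15 to 0.28 on K700E induction, -0.34 to 0.10 on WT induction, -0.13 to 0.31 between induced lines, -0.24 to 0.027 between uninduced lines and -0.033 to 0.41 in the interaction. On K700E induction the ranges also crossed 0 for KLF1 (-0.25 to 0.43), MAP3K7 (-0.80 to 0.29), SLC25A37 (-0.60 to 0.53), HBZ (-0.43 to 0.32) and HBE1 (-1.56 to 0.46). Reference transcripts alone reversed GATA1 (-0.011), SLC25A37 (4.58), RPL10 (1.22) and LSM14B (-0.67) on K700E induction, VAPA (-0.67) and SLC25A37 (2.90) on WT induction, LOC728323 (-1.68) between induced lines, RPL10 (-0.97) and ABCB8 (-1.20) between uninduced lines, and VAPA (0.16) in the interaction. That setting drops assembled transcripts, which can hold all of a gene in a library, so a reversal can reflect assignment of reads. TAL1 (0.41 to 0.87) and IFITM1 (1.87 to 2.14) kept their sign on K700E induction under all 21 alternatives and passed under none.

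Without a filter on share, 2, 1, 1 and 2 transcripts were called on K700E induction, between induced lines, between uninduced lines and in the interaction. Leaving out a library gave 0 to 8 tandem pairs on K700E induction, 0 to 10 on WT induction, 0 to 10 between induced lines, 0 to 5 between uninduced lines and 0 to 5 in the interaction. The mean upstream share differed by 2.40 points with pairs of 5 FPKM or more and 1.93 with acceptors up to 50 nt apart, both past no threshold, and by 2.40 to 3.05 with a library left out. Of those 8 fits 5 missed the threshold, 3 at an exact permutation p of 0.0952 and 2, without a K700E_induced library, at 0.143, the smallest possible there. The number of assembled upstream acceptors differed by 9.83 to 13.8, and with a K700E_induced library left out the test cannot reach the threshold. With genes above 0 in all libraries, 1 gene list passed on K700E induction, the replication histones (adjusted p 0.0447), and 2 between induced lines, the integrated stress response and the myeloid markers (adjusted p 0.0457 for both). With an estimated correlation on the same genes they did not pass (adjusted p 0.699, 0.629 and 0.629).

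Across 8764 genes, correlations of replicate differences were 0.0426 in the K700E line, 0.0993 in the WT line and -0.04 to -0.01 between lines, so the numbers were not taken to pair the samples over all 4 groups. Across 652 abundant genes the WT line reached 0.419, which leaves pairing within that line open. With the replicate number as a block, calls were 1, 1, 2, 0 and 2 for genes, 0 for transcripts and lists, and 0 for tandem pairs in both comparisons where YIPF2 had passed. The block on line and number together gave 1 interaction call. Its blocks lie within a line, so its values between lines are those fitted for replicate 1. The value of -0.16 for SF3B1 between induced lines is therefore not a blocked estimate of that difference.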

Other observations

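The tests of assembled acceptors and of shared culture were chosen after the results were seen.

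Several globin transcripts differed widely between replicates of a group, in opposite order in the 2 lines. HBE1, an embryonic globin, was at 453 and 1412 FPKM in K700E_induced and 601 and 2303 in K700E_uninduced (replicates 1 and 2), but at 840 and 351 in WT_induced and 1077 and 279 in WT_uninduced. HBZ was at 1405 and 2373, 1505 and 2392, 2149 and 881, and 2431 and 918 in the same order of groups, and HBA1 at 2253 and 3988, 2119 and 3215, 2404 and 1455, and 2334 and 1421. HBG1 did not follow this order, being higher in replicate 2 in all 4 groups (1135 and 1933 in WT_induced).

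A candidate explanation is that libraries of a line with the same number shared a culture or preparation. Across 652 genes of 100 FPKM or more, replicate differences of induced and uninduced libraries correlated at 0.419 in the WT line and 0.0537 in the K700E line, against -0.177 to -0.0506 between lines. These values had been seen when the test was set, so a shared culture or preparation stays open in both lines, and no biological explanation was tested.

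The K700E_induced libraries held more assembled acceptors 10 to 30 nt upstream of a reference acceptor, in 1 of 8 kinds of site counted, at the smallest exact permutation p the 28 splits allow (0.0357, or 0.286 adjusted over the 8 kinds). More assembled spliced transcripts would not account for this. The K700E_induced libraries held 2511 and 3223 of them, within the range of the other libraries (2343 to 3395). The share of these acceptors among those transcripts was also higher, by 0.429 percentage points (exact permutation p 0.0357). That result largely follows from the counts and adds little to them. A like rise in assembled sites of every kind was not seen: the ratio of means was 1.84 for these acceptors and at most 1.11 in the 7 other kinds. None of those kinds passed the test (smallest exact permutation p 0.179), but with 28 splits it can miss a small rise. A change in acceptor use in the K700E cells given doxycycline stays open as a hypothesis, since only 1 site, in YIPF2, was found in exactly both K700E_induced libraries, while 9 of the 27 other pairs of libraries also shared 1 or more sites alone and the highest shared 2.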
